A study of Mus musculus with 16 samples.

How the data were processed

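RNA sequencing of the epithelium of bladder and pelvic urethra was taken from 16 libraries of CD-1 mouse embryos at embryonic day 16.5. Per the labels' protocols, tissue was kept in 1% trypsin on ice for 90 minutes, the layers were parted with forceps, and the embryos of one sex of a litter were pooled, so that each of 4 litters gave 4 libraries. Poly(A) RNA was selected from 60 ng of total RNA and made into strand-specific libraries, which were read as pairs of 100 bases, per the labels' protocols.

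The deposited counts are raw reads per gene name. Per the submitters' processing notes, bcl2fastq, HISAT2 2.2.0, SAMtools 1.9, Subread 2.0.6 and DESeq2 were used with the genome build GRCm38. Per the file headers, featureCounts counted reverse-stranded reads on alignments with marked duplicates, and no option was set to count read pairs, to leave out duplicates or to count reads that map to several places. Without pair counting each mate counts on its own: the value 2 stood in 31953 cells of the count table and the value 1 in 17217. Counts therefore carry less information than their number, and reads from near-identical gene copies are partly missing. Mitochondrial genes had 0 counts. The other deposited table holds a normalized signal, gene counts that the authors divided by 1 size factor per library; it was used only to check that relation, which held with a relative spread of at most 9.8e-15. Gene types came from GENCODE M21, which shared 53569 gene names with the count table, 53241 of them at the same chromosome, start and end.

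Total counts were 33062895 to 43286899 per library, so that counting error was small beside the spread between libraries for genes of a few CPM or more. Of 55228 genes, 22309 had 0 counts in every library and 18940 passed edgeR's filterByExpr (minimum count 10), holding 99.95% of the counts. In each group the replicate libraries differed by more than sampling noise (chi-square over degrees of freedom from 18.18 to 77.87 in 24 pairs), and Pearson's r of log2 CPM across genes was 0.968 to 0.9884. Since duplicates were counted, the errors given are SDs and SEs between libraries.

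Libraries were grouped by the region and sex in the labels. With R 4.3.3 and edgeR 4.0.16, counts were scaled by TMM and fitted with 1 mean per group over all 16 libraries (12 residual degrees of freedom, robust quasi-likelihood), and adjusted p values are Benjamini-Hochberg values of the quasi-likelihood F test at a threshold of 0.05. The comparisons were urethra against bladder over both sexes and in each sex, male against female in each region, and the interaction, which is the urethra to bladder difference in males less that in females. SE was the absolute log2 fold change over the square root of F. Scores of lists are mean log2 CPM with a prior count of 2.

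Of 33 gene lists, 31 were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry, which asks whether a list's genes move on balance one way without comparing them with other genes. The lists, the comparisons, the tests and the rule for named genes were fixed before the data were examined. That rule took the 8 genes with the largest difference in each direction between the regions (at least 5 CPM, same sign in all pairs), the 3 called genes per biological list with the smallest p (or 1 gene where none was called), the 2 most abundant genes per list of other cells or stress, sex-linked control genes, up to 8 genes per direction with the smallest p in the sex and interaction tests, and 2 genes per list called there. It gave 190 genes. The text prints 120 of them, and this selection was made after their values were seen. Some other genes are not reported here.

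Litters were shared by the 4 groups, per the labels, so that replicate numbers pair the libraries. Deviations from the group means correlated with a median r of 0.0797 between libraries of the same litter (-0.303 to 0.312, 11 of 24 pairs over 0.1) and -0.023 between litters, across genes. The fit with litter as a block was an alternative. The others were RLE and upper-quartile factors, no filter, a filter of 1 CPM in 4 libraries, no robust estimation, DESeq2 1.42.0, an adjusted p of 0.01, genes not on X or Y, the 2 groups compared alone, a mesenchyme score as covariate, and each library or litter left out.

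The edgeR gene calls and camera at its preset correlation were tested on simulated data. With 100 genes changed 2-fold and 100 changed 4-fold, 85% and 97% were recovered for the region comparison over 18619 genes, 69% and 90% for females, and 73% and 91% for males. The shares were 71% and 89% for sex in bladder over 18604 genes, and 78% and 95% for sex in urethra and 58% and 86% for the interaction over 18641 genes. In those runs 0 of 30 unchanged lists were called. The simulated genes varied independently of each other, so that these runs cannot show how camera behaves where genes move together. In a split of the real bladder libraries with 0 called genes, camera called 21 lists.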

Results

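RNA was measured in the epithelium of the bladder and of the pelvic urethra, the upper part of the tube that drains the bladder, from CD-1 mouse embryos at embryonic day 16.5. The epithelial layer had been peeled from the mesenchyme after trypsin treatment, and the embryos of each sex of a litter were pooled. Each of 4 litters gave 1 library of female bladder, male bladder, female urethra and male urethra epithelium, so that there were 16 libraries in 4 groups of 4. Total gene counts per library were 34444211 to 39634297 in female bladder, 33062895 to 39762574 in male bladder, 33307250 to 43286899 in female urethra and 35198378 to 42657609 in male urethra. Of 55228 genes in the table, 18940 were tested. Levels are CPM, gene counts relative to the TMM-scaled library total, given as mean ± SD. Differences are log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and "called" means an adjusted p under 0.05. Positions are 1-based on GRCm38, from the count table.

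The sex labels were checked with sex-linked genes first. Transcripts of the Y chromosome genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to at least 229 CPM in each library labelled male and to at most 1.77 CPM in each library labelled female. Xist, the non-coding RNA of the inactive X chromosome, was at least 354 CPM in the female libraries and at most 6.96 CPM in the male ones. In a principal component analysis of the 2000 most variable genes, the first component held 65.7% of the variance and separated bladder (scores from -74.8 to -29.9) from urethra (42.1 to 64.7). The second component held 10.7% and separated female urethra (-28 to -20.8) from male urethra (16.5 to 48.8). The sexes did not overlap in bladder either, on the first component (female -53.2 to -29.9, male -74.8 to -60.2) or on the second (female -21.6 to 1.03, male 3.79 to 13.6).

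The study set out to find genes specific to the bladder or the urethral epithelium. Of all 18940 genes tested 60.4% were called between the regions over both sexes, 5755 higher and 5678 lower in urethra. The member counts of lists given below for this comparison are to be read against these numbers. Genes of the differentiated urothelium, the lining of the bladder, were lower in urethra. The uroplakin gene Upk1b, whose protein is part of the plaques on the urothelial surface, stood at 2055 ± 373 CPM in bladder and 461 ± 78 CPM in urethra (SD, n = 8 each, log2 difference -2.16 ± 0.10, adjusted p = 1.49e-10 in edgeR). Upk1a (-2.13 ± 0.09) and Rab27b, a small GTPase of vesicle transport (-1.73 ± 0.08), were lower as well. Of the 18 genes of the urothelial list 14 were lower in urethra, 3 were higher and 1 was not called (median log2 difference -1.74). Keratins of simple epithelium, Krt18 (-1.99 ± 0.10) and Krt8 (-1.33 ± 0.08), were lower in urethra too, within a general epithelial list of 15 genes with 3 higher and 5 lower.

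Genes of basal and stratified squamous epithelium were higher in urethra. Krt14, a basal keratin, rose from 18.3 ± 7.79 CPM in bladder to 342 ± 78.7 CPM in urethra (18.5-fold, adjusted p = 2.43e-09 in edgeR), and Col17a1, a hemidesmosome collagen, was 10.1-fold higher. Krt5, the partner of Krt14, was abundant in both regions, at 1020 ± 164 CPM in bladder and 2398 ± 383 CPM in urethra. Of 13 basal genes 9 were higher in urethra and 1 lower, and of 18 squamous genes 13 were higher and 3 lower. Lor, which encodes the cornified envelope protein loricrin, was 13.5-fold higher in urethra, while the envelope precursors Sprr1a (-2.13 ± 0.10) and Ivl (-3.25 ± 0.16) of the same list were lower.

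**Figure D1:**
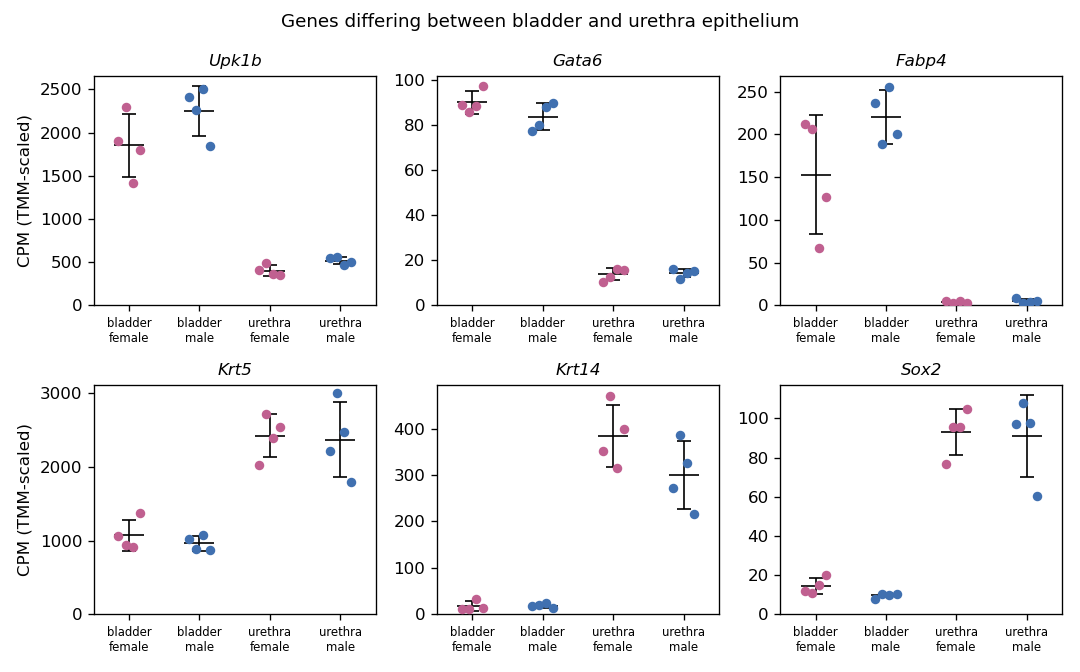
CPM (vertical axis, linear, from 0) of 6 genes in the 4 groups (horizontal axis), with single libraries as points (n = 4 per group), means as horizontal marks and ± 1 SD as bars. Upk1b, Gata6 and Fabp4 lie higher in all 8 bladder libraries than in any urethra library, and Krt5, Krt14 and Sox2 lie higher in all 8 urethra libraries.

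Of 30 transcription factors with regional roles 19 were higher and 9 lower in urethra. Gata6, on chromosome 18 from 11052064 to 11085635, was 6.16-fold higher in bladder (87 ± 6.18 against 14.1 ± 2.22 CPM). Sox2, on chromosome 3 from 34650405 to 34652461, was 7.73-fold higher in urethra (91.9 ± 15.8 against 12.1 ± 3.82 CPM), and the posterior HOX genes Hoxd13 (2.23 ± 0.19) and Hoxa13 (0.95 ± 0.09) were higher there, with 5 of 14 posterior HOX genes higher and 1 lower. The largest differences toward urethra among genes that moved the same way in all 8 litter and sex pairs were Pax9, a paired-box factor on chromosome 12 from 56691767 to 56712822 (69.4-fold, adjusted p = 3.65e-07 in edgeR), Mroh4 (66.6-fold), the keratin Krt2 (66.35-fold), the p53 relative Trp73 (59.2-fold), the mucin Muc4 (56.6-fold), the LIM homeobox factor Lhx1 (54.9-fold), Arhgef38 (50.9-fold) and the keratin Krt17 (49.3-fold). Lhx1 was found mainly in female urethra, at 10.7 to 20 CPM, against 0.0593 to 0.362 CPM in male urethra replicates 1 to 3 and 3.82 CPM in replicate 4. It had 0 counts in 4 of the 8 bladder libraries, and Trp73, Pax9, Mroh4 and Arhgef38 had 0 counts in 1 or 2 of them, so that these folds and their order depend on the prior count. Toward bladder they were Ckm (65.2-fold), Popdc2 (56.7-fold), Pln (44.1-fold), Sptssb (41.4-fold), the fatty acid binding protein gene Fabp4 (41.2-fold), the thyroid hormone carrier gene Ttr (34.5-fold), Acta1 (33.3-fold) and P2rx1 (30.8-fold). Of these, Ckm, Popdc2, Pln, Acta1 and P2rx1 are known from muscle; Pln had 0 counts in 2 urethra libraries.

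Genes of the WNT, FGF and retinoic acid lists were mostly higher in urethra. Of 18 targets of WNT and beta-catenin 14 were higher and 2 lower, among them Apcdd1 (2.64 ± 0.14) and the receptor gene Fzd10 (2.48 ± 0.09). Of 25 WNT ligands and inhibitors 15 were higher and 3 lower: Wnt6 was 8.14-fold and Wnt10b 32.6-fold higher in urethra, and Wnt11 was 4.98-fold higher in bladder. FGF genes (16 of 20 higher, 1 lower) included Fgf1 (1.87 ± 0.09) and the FGF-responsive factor Etv4 (4.57 ± 0.24). Retinoic acid genes (12 of 17 higher, 1 lower) included Crabp2 (3.63 ± 0.28) and the receptor gene Rarg (1.06 ± 0.08). Of the 7 genes of the steroid receptor list, which holds the estrogen-responsive cofactor gene Greb1 beside receptor genes, 6 were higher in urethra and 1 lower: the progesterone receptor gene Pgr (1.97 ± 0.17) and Greb1 (2.98 ± 0.29) were among those higher. The tight junction gene Cldn3 was 16.2-fold higher in urethra, the mucin gene Muc1 was 12.2-fold higher, and the BMP ligand gene Bmp3 was 6.72-fold higher in bladder. The 11 of 15 Wolffian and Müllerian duct genes that were higher in urethra (1 lower) included Npnt (1.16 ± 0.11) and Gata3 (0.71 ± 0.08).

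Metabolic and proliferation genes were higher in bladder. All 19 genes of cholesterol synthesis were lower in urethra (median -0.66), for example Mvd (-1.07 ± 0.06) and Msmo1 (-1.15 ± 0.09), and so were 13 of 19 PPAR and lipid genes, among them Acadl of fatty acid oxidation (-1.77 ± 0.09), against 2 that were higher. All 28 cell cycle genes were lower in urethra (median -0.71), including the cyclin genes Ccnb2 (-1.17 ± 0.07) and Ccna2 (-1.12 ± 0.07). Of 15 genes of the prostate and androgen list 10 were higher and 4 lower, with Tmprss2 lower (-2.14 ± 0.09).

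Markers of other tissues differed between the regions too. Smooth muscle genes were higher in bladder (11 of 12, median difference -3.29): Acta2 stood at 1079 ± 458 CPM in bladder and 107 ± 103 CPM in urethra, and Myh11 was 13.5-fold higher in bladder. All 12 endothelial genes were lower in urethra (Cdh5 -1.15 ± 0.32), and the collagen gene Col1a1 was 3.83-fold higher in bladder, with 11 of 20 mesenchyme genes lower and 2 higher in urethra. All 8 red blood cell genes were lower in urethra (Hbb-bs -1.06 ± 0.21). Leukocyte genes gave 1 lower and 13 not called of 14, with Lyz2 at 65.7 ± 15.5 CPM in bladder and 66 ± 21.8 CPM in urethra and the macrophage receptor gene Csf1r at 20.03 ± 4.12 and 18.9 ± 4.77 CPM. The neuroendocrine list had 6 of 10 genes higher in urethra and none lower; Syp, not called, was at 4.22 ± 0.918 and 5.83 ± 4.13 CPM. Of 18 dissociation stress genes 7 were higher in urethra and 3 lower, with Jund at 1.14 ± 0.08 and Hsp90aa1 at -0.46 ± 0.07. Camera did not call 16 of the 31 lists. Of those with counts given above these were the general epithelial (adjusted p = 0.252), regional transcription factor (0.056), posterior HOX (0.136), androgen (0.795), mesenchyme (0.0742), red blood cell (0.0632), leukocyte (0.806) and dissociation stress (0.156) lists. The others gave 8 higher and 2 lower of 15 hedgehog genes, 11 and 6 of 27 BMP genes, 8 and 2 of 17 Notch genes, 6 and 6 of 18 tight junction genes, and 6 and 4 of 14 mucin genes. Among markers not called, 6 of 14 skeletal muscle genes were higher and 7 lower, 2 of 16 neuron and glia genes were higher, and 2 of 8 intestinal genes were higher and 4 lower. The median and the mean differed in sign for the neuron and glia genes (-0.0441 and 0.18) and for the general epithelial genes (0.0412 and -0.157).

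Across both sexes 11433 genes were called, 5755 higher and 5678 lower in urethra, of which 3490 differed at least 2-fold. Adjusted over the list alone, 10 Notch genes were higher, and the counts of the other lists were those given. Camera with its preset correlation called 15 of 31 lists. With an estimated correlation none was called, 5 lists had an unadjusted p under 0.05 and fry called 25. The adjusted p values with an estimated correlation were 0.21 for the urothelial list, 0.38 for the basal and squamous lists, 0.21 for WNT targets, 0.428 for WNT ligands, smooth muscle and the duct list, 0.126 for the FGF and PPAR lists, 0.215 for retinoic acid, 0.319 for steroid receptors, cholesterol synthesis and cell cycle, 0.592 for endothelium and 0.512 for neuroendocrine genes. With the smooth muscle score of each library as a covariate, chosen after the data were seen, the SE of Upk1b went from 0.101 to 0.241, 5861 genes were called, and 9 of the genes named above in this comparison lost the call, as did Actc1 and Kdr (-3.52 to 0.01 and -0.87 to 0.06). The score did not overlap between bladder (6.46 to 8.51 log2 CPM) and urethra (3.77 to 6.18), so this fit cannot part muscle from region. The difference shrank toward 0 for Ckm (-6.03 ± 0.62 to -1.10 ± 0.50), Acta1 (-5.06 ± 0.53 to -1.49 ± 0.69), Hbb-bs (-1.06 ± 0.21 to -0.04 ± 0.44), Gata3 (0.71 ± 0.08 to 0.30 ± 0.17), Acta2 (-3.52 ± 0.42 to -0.27 ± 0.26) and Myh11 (-3.76 ± 0.49 to 0.18 ± 0.28), and the score itself holds Acta2 and Myh11. For P2rx1 (-4.94 ± 0.57 to -2.62 ± 1.23) and Col1a1 (-1.94 ± 0.31 to -0.55 ± 0.69) the difference shrank and the SE grew. For Cdh5 (-1.15 ± 0.32 to -0.94 ± 0.85) the difference stayed about as large and the call ended with the larger SE; it was also lost without litter 1 (-0.88, adjusted p = 0.0681 in edgeR) and with the mesenchyme score as a covariate, where the difference fell to -0.47 (0.0588).

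Urethra and bladder were also compared within each sex. Sox2, for example, was higher in urethra by 2.67 in females and 3.23 in males on the log2 scale, and Gata6 differed by -2.71 and -2.54. All 28 cell cycle genes were lower in male urethra than in male bladder, and 21 of them in females; the adjusted p of this list was 0.231 and 0.536 with an estimated correlation. In females 8838 genes were called (4470 higher and 4368 lower in urethra) and in males 9720 (4850 higher and 4870 lower). The comparisons share no libraries. They had 3321 of the genes higher in urethra in common, where independent lists would share 1145, and 3256 of the lower ones, where independent lists would share 1123. The fold changes in the 2 sexes correlated at r = 0.799 across genes, which are not independent replicates. With the smooth muscle covariate the counts were 4880 in females and 5866 in males.

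Male and female epithelium was then compared within the bladder. Besides the sex chromosome genes few differences were called: 14 genes in all, 6 of them not on X or Y (1765 had an unadjusted p under 0.05). Of these 6 genes 5 were lower in males: the collagen gene Col8a1 (2.67 ± 1.23 against 20.2 ± 10.7 CPM, SD, n = 4 each, log2 difference -2.92 ± 0.42, adjusted p = 0.00899 in edgeR), Rab11fip4 (-0.68 ± 0.10), Syt9 (-0.88 ± 0.14), Mtmr7 (-1.50 ± 0.24) and Gm28437 (6.56 ± 0.772 against 58.8 ± 8.03 CPM). Gm28437 is annotated as an unprocessed pseudogene on chromosome 1 from 24613189 to 24613971, and its reads cannot be assigned with certainty where a near-identical copy exists elsewhere. Upk1a was 1601 ± 224 CPM in males and 1231 ± 231 CPM in females and was not called, and neither was Snx31 (0.53 ± 0.15).

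Neuron and glia genes had a median male minus female difference of -1.69, with Phox2a at -2.37 ± 0.66 and Isl1 at -1.05 ± 0.28, and neuroendocrine genes had a median of -1.78, with Scg3 at -2.36 ± 0.57; no member of either list was called over all genes, and 10 of 16 and 7 of 10 were when adjusted over the list alone. Of the 7 genes of the steroid receptor list 5 were lower in males adjusted over the list alone. The neuron and glia scores of female bladder replicates 1 to 3 were 3.77, 3.93 and 3.44 (mean log2 CPM), against 1.41 in replicate 4 and 0.93 to 2.79 in male bladder. Camera called 20 of 31 lists, 5 toward males (among them urothelial, cholesterol synthesis and smooth muscle genes) and 15 toward females. With an estimated correlation the adjusted p was 0.254 for the neuron, neuroendocrine, urothelial and cholesterol lists and 0.358 for smooth muscle, and it lay from 0.205 to 0.726 over all 20. It was 0.205 for steroid receptors, 0.254 for regional transcription factors, Notch, retinoic acid and PPAR genes, 0.274 for FGF and duct genes, 0.307 for red blood cell and 0.348 for HOX and hedgehog genes. It was 0.461 for WNT ligands, 0.491 for leukocyte and general epithelial, 0.62 for endothelial and 0.726 for cell cycle genes. Adjusted over the list alone, 1 gene each of the hedgehog, WNT ligand, Notch and retinoic acid lists was lower and 1 of the cholesterol list higher in males, and no gene of the other called lists beside the 3 named above was called in this way. Of all lists, fry called 0 lists, 8 at an unadjusted p under 0.05. The number of called genes was 81 without female bladder replicate 4, 9 without male bladder replicate 3, and 7, 8, 6 and 25 without litters 1, 2, 3 and 4; without litter 1, 12 lists were called. DESeq2 called 156, and 2 genes were called when adjusted over the genes not on X or Y alone. With litter as a block Mtmr7 and Gm28437 were not called (adjusted p = 0.0552 each in edgeR), and each of the 5 named genes lost its call in some fit with a library or litter left out, Col8a1 for example without litter 2 (adjusted p = 0.177 in edgeR) and Rab11fip4 without litter 1 (0.188).

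In the urethra the sexes differed widely. Ly6a, which encodes the cell surface antigen Sca-1, lies on chromosome 15 from 74994877 to 74998031 and stood at 52.4 ± 17.2 CPM in males and 2.97 ± 0.523 CPM in females (17.6-fold, n = 4 each, adjusted p = 2.97e-07 in edgeR). Fkbp5, a co-chaperone of steroid receptors, was 3.29-fold higher in males and Sgk1, a kinase known to respond to steroid hormones, 7.36-fold. The ligand gene Bmp2 (2.45 ± 0.17), the guanine deaminase gene Gda (2.46 ± 0.15), the serine protease gene Prss32 (3.26 ± 0.22), Tmem37 (3.18 ± 0.23) and Tmem158 (1.97 ± 0.14) were also higher in males, in 4 of 4 litters each, as were Fkbp5, Sgk1 and Ly6a. Of 15 prostate and androgen response genes 8 were higher in males and 2 lower, with the zinc finger factor Zbtb16 at 34.4-fold.

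Lower in male urethra were the tight junction gene Cldn6, on chromosome 17 from 23679249 to 23682446 (77.3 ± 5.32 against 169 ± 15.6 CPM), the kinase gene Nuak1 (7.83-fold), the circadian repressor gene Bhlhe41 (5.53-fold), the oxytocin receptor gene Oxtr (28.9-fold), Susd1 (-1.14 ± 0.08), Nup210 (2.006-fold), Shisa2 (-1.45 ± 0.12) and Skil (-1.13 ± 0.10), in 4 of 4 litters each. Wnt7a, a ligand of the female reproductive tract, was 112.5 ± 16.9 CPM in female and 1.2 ± 0.839 CPM in male urethra, and the homeobox gene Msx1 was 56.25 ± 9.59 and 2.355 ± 1.06 CPM; this gene and Wnt7a fall outside the naming rule for this comparison and were chosen after their values were seen. Genes of the steroid receptor list were lower in males (4 of 7), among them Pgr (-1.35 ± 0.23) and Greb1 (-2.72 ± 0.38). Of 15 genes of the duct list 6 were lower in males and 3 higher, and camera did not call the list (adjusted p = 0.713). Among the lower ones Pax2, chosen after its values were seen, stood at 21.4 ± 3.21 CPM in female and 2.29 ± 2.84 CPM in male urethra, and Lhx1 at 14.1 ± 4.09 and 1.09 ± 1.82 CPM.

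**Figure D2:**
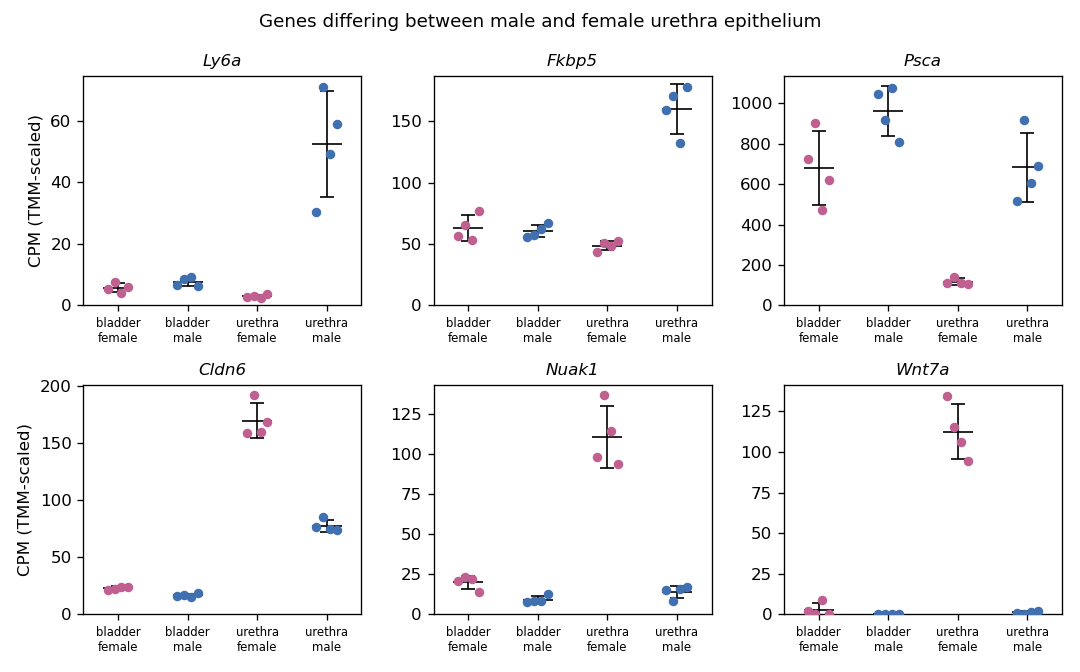
CPM (vertical axis, linear, from 0) of 6 genes in the 4 groups (horizontal axis), with single libraries as points (n = 4 per group), means as horizontal marks and ± 1 SD as bars. Ly6a, Fkbp5 and Psca lie higher in all 4 male than in all 4 female urethra libraries, and Cldn6, Nuak1 and Wnt7a lie lower.

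Urothelial genes were higher in male than in female urethra (12 of 18, none lower), with Psca at 683 ± 171 against 116 ± 17.4 CPM and Mal 2.22-fold higher. Squamous genes gave 7 higher and 2 lower of 18, with Lor (1.58 ± 0.17) and Sprr1a (0.89 ± 0.13) higher, and basal genes 5 higher of 13, with the laminin gene Lamb3 at 0.85 ± 0.13. The retinaldehyde dehydrogenase gene Aldh1a1 was 4.38-fold and Rarg 1.53-fold higher in males, while 13 of the 17 retinoic acid genes were not called. The keratin gene Krt19 (0.57 ± 0.11) was among 5 of 15 general epithelial genes higher in males. Cell cycle genes were lower in males (19 of 28, none higher), among them Mcm7 (-0.50 ± 0.08) and Bub1b (-0.56 ± 0.09). Endothelial genes were higher in male urethra (9 of 12; Plvap 1.69 ± 0.45, Cldn5 1.61 ± 0.44), and smooth muscle genes had a median difference of 1.32 with none called (Acta2 1.62 ± 0.56).

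Adjusted over the list alone, the counts higher and lower in males were 14 and 0 urothelial, 8 and 2 androgen response, 0 and 5 steroid receptor, 6 and 0 basal, 8 and 4 squamous, 3 and 1 retinoic acid, 7 and 1 general epithelial, 0 and 24 cell cycle, 10 and 0 endothelial and 6 and 0 smooth muscle genes.

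In all, 3786 genes were called between the sexes in urethra, 2030 higher and 1756 lower in males, 3647 of them not on X or Y. With upper-quartile scaling the split turned to 1821 higher and 2523 lower. Camera called 10 lists; with an estimated correlation none was called (3 at an unadjusted p under 0.05), and fry called 7. The adjusted p with an estimated correlation was 0.478 for the urothelial, 0.175 for the androgen and 0.47 for the steroid receptor list, 0.739 for the retinoic acid and cell cycle lists, and 0.801 for the basal, squamous, general epithelial, smooth muscle and endothelial lists. The number of called genes was 2200, 2015 and 2156 without litters 1, 3 and 4, and 2056 without female urethra replicate 1 and male urethra replicate 2, chosen after the data were seen; without female urethra replicate 1 Plvap and Cldn5 were not called (adjusted p = 0.0522 and 0.0646 in edgeR) and 5 lists were, against 6 without litter 1. Plvap and Cldn5 were not called without litter 1 or 4 either, nor was Cldn5 without female urethra replicate 4 or male urethra replicate 3 (adjusted p of up to 0.0967 in edgeR). With the smooth muscle score as a covariate neither Plvap nor Cldn5 was called (adjusted p = 0.0713 and 0.053 in edgeR). Plvap was also not called without female bladder replicate 3 and male urethra replicate 4 (0.0565). The smooth muscle list was not called without 1 of 6 single libraries (female bladder 4, female urethra 1, 3 and 4, male urethra 1 and 4) or without litter 1 or 4 (adjusted p of up to 0.332 in camera). With litter as a block the smooth muscle list was no longer called (adjusted p = 0.0624 in camera).

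Whether the difference between urethra and bladder depended on sex was tested directly. Of 714 genes called, 695 were not on X or Y, and 674 of these were also called by sex in urethra while 1 was called by sex in bladder. That gene was Col8a1, named after its values were seen. Positive values included Prss32 (3.27), Ly6a (3.73), Sgk1 (2.91), Tmem37 (3.17), Fkbp5 (1.77), Tmem158 (2.03) and Pea15a (0.81), with adjusted p values from 6.08e-05 to 6.57e-05 in edgeR. The sign does not tell in which sex the regional difference was larger. Of the 695 genes, 306 had a smaller absolute urethra to bladder difference in males than in females. Il31ra, an interleukin receptor gene, was at 2.07 ± 0.68 CPM in male urethra, 0.276 ± 0.177 CPM in female bladder, 0.156 ± 0.0484 CPM in male bladder and 0.00658 ± 0.0132 CPM in female urethra (adjusted p = 7.12e-05 in edgeR); near 0 its fitted difference depends on the prior count. Mme, the neprilysin gene, was at 148 ± 5.55 CPM in male and 17 ± 5.14 CPM in female urethra and was 10.5 ± 6.37 and 6.75 ± 3.75 CPM in female and male bladder. Of signalling genes Wnt4 (1.31), Bmp2 (1.95), Ihh (1.71), Fgfr3 (0.75), Smad6 (0.62) and Aldh1a1 (2.30) had positive values and Fgf9 (-2.54) a negative one. The secretory gene Agr2 (1.42), the neuropeptide gene Calca (4.19), Psca (2.06), Lor (1.34) and the mucin Muc4 (2.67), chosen after its value was seen, were positive, and Susd1 (-1.14), Shisa2 (-1.49), Bhlhe41 (-2.42), Ass1 of arginine synthesis (-1.74), Dnajc6 (-2.42), C1qtnf12 (-1.75), Fam210b (-1.40), Mvd (-0.58) and Mcm7 (-0.53) were negative.

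Of the 714 genes 471 were positive and 243 negative; with upper-quartile scaling 518 were positive and 433 negative. Among lists, camera called 17 with positive and 2 with negative values (cholesterol synthesis, median -0.39, and cell cycle, median -0.29), and with an estimated correlation none (2 at an unadjusted p under 0.05); fry called 2. The adjusted p with an estimated correlation lay from 0.117 to 0.698, at 0.117 for prostate and androgen response, 0.212 for retinoic acid, 0.466 for hedgehog, BMP and Notch, 0.477 for mucins and cholesterol synthesis, 0.496 for urothelial, HOX, basal, WNT ligand, FGF and cell cycle genes and 0.558 for squamous and leukocyte genes. Markers of endothelium (median 1.97, Cldn5 2.31), mesenchyme (0.80, Twist1 2.36), neurons and glia (1.39) and neuroendocrine cells (1.67) had positive medians as well, with adjusted p of 0.477, 0.698, 0.496 and 0.496 with an estimated correlation. Adjusted over the list alone, the positive and negative genes were 6 and 1 urothelial, 8 and 3 androgen response, 3 and 0 HOX, 6 and 0 hedgehog, 5 and 0 BMP, 4 and 0 retinoic acid, 3 and 1 mucin, 3 and 0 WNT ligand, 1 and 1 FGF, 1 and 0 basal and 1 and 0 squamous genes. Also called were 10 endothelial, 1 mesenchyme and 1 neuroendocrine gene with positive values, and 9 cholesterol synthesis genes and 1 cell cycle gene with negative values. The count was 246, 303, 221 and 264 without litters 1, 2, 3 and 4. It was 453 without female bladder replicate 1, 446 and 382 without male bladder replicates 1 and 2, 434 without female urethra replicate 4 and 379 without male urethra replicate 3, and it was 1197 with the mesenchyme score as a covariate and 1477 in DESeq2; with litter as a block Twist1 was not called (adjusted p = 0.0625 in edgeR). Agr2, Calca, Cldn5, Fgf9, Fgfr3, Ihh, Lor, Mcm7, Mvd, Smad6, Twist1 and Wnt4 each lost the call in some fit with a library or litter left out (adjusted p of up to 0.291 in edgeR, for Twist1 without litter 1).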

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

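The tests of mesenchyme carry-over, halved urethra counts, duct tissue dilution, the leukocyte against the smooth muscle list, admixture in female bladder replicate 3, swapped sex labels and duct epithelium were chosen after the values they rest on were seen, the smooth muscle covariate was added then too, and the wording of the smooth muscle patterns, the gene list and bound of the duct dilution test, and the reading of the thinning to the same total were changed after their results. The urethra to bladder difference depended on sex for 714 genes. By the interaction, in log2 units (difference in males less that in females), Il31ra was 8.5544, a fitted value that depends on the prior count, since female urethra held 1 count in 1 of 4 libraries, and that was not ranked. The largest other named positive values were Zbtb16 4.4322, Calca 4.1871, Mme 3.7605, Ly6a 3.7319, Prss32 3.2661 and Tmem37 3.166. Sgk1 was 2.9054, Col8a1 2.7457, Muc4 2.6657, Twist1 2.364, Cldn5 2.3137, Aldh1a1 2.3019, Psca 2.0581, Tmem158 2.0292, Bmp2 1.948, Gda 1.8485, Fkbp5 1.7695 and Ihh 1.7122. Agr2 was 1.4228, Lor 1.3352, Wnt4 1.307, Wnt11 1.1079, Lamb3 0.8175, Pea15a 0.80963, Fgfr3 0.74912 and Smad6 0.61611. Negative values were Oxtr -3.3614, Msx1 -2.9303, Fgf9 -2.5383, Bhlhe41 -2.4223, Dnajc6 -2.4174, Nuak1 -1.8395, C1qtnf12 -1.7487, Ass1 -1.7437, Shisa2 -1.4949, Fam210b -1.4007, Susd1 -1.1351, Skil -0.90604, Nup210 -0.85328, Krt18 -0.79717, Cldn6 -0.67241, Mvd -0.57595 and Mcm7 -0.53437. Among lists the interaction medians were 0.224 for urothelial, 0.317 for posterior HOX, 0.754 for androgen response, 0.424 for basal, 0.407 for squamous, 0.456 for hedgehog, 0.786 for WNT ligand, 0.448 for BMP, 0.336 for FGF, 0.455 for Notch, 0.658 for retinoic acid and 0.827 for mucin genes. They were -0.39 for cholesterol synthesis, -0.291 for cell cycle, 0.797 for mesenchyme, 1.97 for endothelium, 0.459 for leukocytes, 1.39 for neurons and glia and 1.67 for neuroendocrine genes. None of these lists was called with an estimated correlation (adjusted p from 0.117 to 0.698), 2 lists had an unadjusted p under 0.05 and fry called 2.

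A sample far from the other 3 of its group was found in 49 of 616 groups of values, where chance gives about 1 in 20, or 30.8. Over all 190 genes of the naming rule it was 52 of 760, where chance gives 38. Female bladder replicate 3 held 11 of the 49: Pax9 2.01, Trp73 0.735, Krt17 27, Acta1 330, Krt14 34, Wnt10b 0.955, Apcdd1 48.1, Etv4 3.87, Crabp2 18.8 and Muc1 1.42 CPM, and a WNT target score of 4.68. In female bladder replicate 4 the neuroendocrine score was -2.35, and Phox2a was at 0.839, Zbtb16 at 13.5, C1qtnf12 at 14.3 and Calca at 0.0579 CPM. In female bladder replicate 2 the Y-linked score was -1.24 and Eif2s3y 0.436 CPM. In male bladder replicate 1 the FGF score was 2.84, the red blood cell score 2.95, Lyz2 41.4, Gm28437 5.41 and Sgk1 10.8 CPM. Replicate 2 had Col1a1 at 2550 CPM, replicate 4 had Nuak1 at 12.6 CPM, and replicate 3 had a basal score of 7.33, with Pax9 at 1.47, Lhx1 at 0.0587, Syp at 5.66 and Calca at 0.587 CPM. In female urethra, replicate 1 had Tmem158 at 25.4 and Calca at 1.11 CPM, replicate 2 Krt17 at 488 and Psca at 142 CPM, replicate 3 a HOX score of 3.54, Ttr at 12.9 and Fzd10 at 113 CPM, and replicate 4 Gm28437 at 25.3 and Il31ra at 0.0263 CPM. In male urethra replicate 2 the regional transcription factor score was 3.25, the WNT target score 4.95, Sgk1 187, Krt19 1930 and Msx1 0.771 CPM. Replicate 1 had Bhlhe41 at 8.35 CPM, replicate 3 Kdm5d at 64.8 and Scg3 at 2.12 CPM, and replicate 4 Lhx1 at 3.82 and C1qtnf12 at 21.7 CPM.

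Many genes (3786) differed between the sexes in urethra and few (14) in bladder. With the mesenchyme score as a covariate 4566 were called in urethra, which argues against unequal mesenchyme as the whole cause. Thinning to the same total count gave 3769 and decided nothing, since the totals differed at most 1.31-fold before it. With the counts of every urethra library halved, to 16656141 to 21642914 against a lowest bladder total of 33062895, 3598 genes were called, which argues against more counts in urethra as the whole cause. Over the 3647 autosomal genes called in urethra, the bladder difference was a median of 0.114 of that in urethra (quartiles -0.0774 to 0.314). The fit used a shared spread per gene over all libraries, so a larger spread in bladder would weaken both sex comparisons. The ratio therefore does not test such a spread as the reason for the few calls in bladder. The genes were also picked by their call in urethra, which by itself lowers the ratio. Of these genes 1972 were higher in males. If duct tissue had diluted female urethra, genes of stratified epithelium, which the simple epithelium of the ducts is taken to lack, would be diluted in full. For 633 genes the male minus female difference less 2 SE lay above the upper quartile of the basal list (0.488), and for 255 above its highest member (0.848), which argues against such dilution as the whole cause of the genes higher in males. Dilution as a part of it stays open. The sex of the embryos itself as the cause stays open, since sex goes with the preparation.

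Smooth muscle transcripts were higher in bladder libraries, and so were urothelial and other genes. The leukocyte list median lay 3.28 log2 units above that of the smooth muscle list, more than the 0.472 of their summed SEs, which argues against a lower share of epithelium overall as the whole reason, since that would raise the markers of every other tissue alike. Endothelial (-1.24), red blood cell (-1.07) and mesenchyme genes (-0.683) had medians toward bladder as well, and a lower share as a part of the reason stays open. Outside the smooth muscle list, the 1587 genes at least 2-fold higher in bladder followed the smooth muscle score within groups with a median r of 0.0944 and the 1892 higher in urethra with 0.187, a difference of -0.0924. As a set, the bladder-higher genes thus did not follow muscle within groups more than the urethra-higher genes did. The test cannot see muscle that differs between the regions, and a median does not speak for single genes such as Ckm and Acta1. It says nothing on the amount of muscle itself: the smooth muscle score ranged from 6.46 to 8.46 log2 CPM in female bladder and from 3.77 to 6.18 in male urethra. With the smooth muscle score as a covariate all 14 urothelial genes lower in urethra kept the call, while the urothelial list members higher in urethra lost it. The score did not overlap between the regions, so this fit cannot part muscle from region. Added muscle would also dilute urothelial transcripts and not raise them, so the kept calls decide nothing on muscle. Whether the smooth muscle transcripts come from carried-over wall stays open, and a difference between the tissues was not tested apart from it.

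Genes of the duct list such as Pax2 and Lhx1 were high in female urethra and traceable in female bladder replicate 3. For that library the excess over the mean of the other female bladder libraries was taken as a share of the female urethra level. Its median was 6.99% for 87 urethra genes not called between the sexes and 7.45% for 56 female-higher genes. The ratio was 0.938, as admixture of urethral epithelium would give, so that this may be a candidate explanation. A swap of sex labels is excluded, since Y-linked transcripts in libraries labelled female reached at most 0.741% of the male mean. Lower levels in male urethra for 6 members of the list cannot be told apart from duct epithelium in the female preparation, since sex goes with the preparation. A biological difference between the sexes stays open.

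Other splits of the libraries were compared with the real one. For region over both sexes, 1 of 100 splits called as many genes as the real 11433 (highest other 8001). For females it was 1 of 35 (8838, highest other 287), and for males 1 of 35 (9720, highest other 2). For sex in urethra it was 1 of 35 (3786, highest other 225). These shares argue against chance but cannot exclude it, since no share of 35 splits can fall below 1 of 35. In splits that mix groups, the real difference also adds to the spread within groups, which lowers their counts. For the interaction it was 2 of 100 (714, highest other 869). The split with 869 kept the sex labels in urethra and mixed those in bladder, and it called more genes than the real one. The share thus does not exclude chance for the bladder side of the interaction. For sex in bladder it was 2 of 35 (14, highest other 129), which does not exclude chance. The split with 129 exchanged female bladder replicate 4 and male bladder replicate 3. It called several times the real count, which points to a structure of these samples. Of lists, as many were called in 30 of 100 splits for region (15, highest other 21). For sex in bladder it was 3 of 35 (20, highest other 21), and in urethra 22 of 35 (10, highest other 17). Chance is not excluded for these. For the interaction it was 4 of 100 (19, highest other 21). That share is under 0.05 for the preset correlation only, since no list was called with an estimated one, and it leaves chance open. Among splits that parted every litter pair, as the real one does, the highest other gene count was 0 in 8 splits each for females, males and both sex comparisons and in 7 for the interaction, and 8001 in 8 splits for region. For lists it was 20, 21 and 17 in 8 splits each for region, sex in bladder and sex in urethra, and 18 in 7 splits for the interaction, against the real 19; so few splits cannot give a share under 0.05.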

How the results depend on the processing

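The settings with halved counts, with the smooth muscle score as a covariate, without the 2 libraries with duct markers (female bladder replicate 3 and male urethra replicate 4), and without female urethra replicate 1 and male urethra replicate 2 were chosen after the data were seen. Litter as a replicate block, which follows the pairing, gave 11496 genes for region, 8919 in females, 9805 in males, 13 and 3874 for sex in bladder and urethra and 838 for the interaction. Lists called under the block were 17, 20, 11 and 19 for region, sex in bladder, sex in urethra and interaction. The block ended the calls of Mtmr7 and Gm28437 in bladder, of Twist1 and Erg in the interaction and of the smooth muscle list in urethra, added those of Krt7, Hoxd9 and Hoxa11 in the interaction, and changed no other call of a gene reported here or ended that of another list. With the smooth muscle score as a covariate the region count was 5861, 4880 in females and 5866 in males, and 44 genes were called by sex in bladder. The score did not overlap between the regions, so these region counts cannot part muscle from region. With the mesenchyme score the bladder sex count was 29 and the interaction count 1197. DESeq2 called 156 by sex in bladder and 1477 for the interaction. At an adjusted p of 0.01 the urethra sex count was 1731 and the interaction count 207, and among genes not on X or Y alone 2 were called in bladder. Without the 2 libraries rich in nuclear RNA or poor in mesenchyme markers these counts were 2056 in urethra and 432 for the interaction. Without the 2 libraries with duct markers no count moved over 1.5 times. With an estimated correlation 0 lists were called in each of the 4 comparisons, and fry called 25 for region, 0 for sex in bladder and 2 for the interaction. Leaving out each library or litter gave 10148 to 11703 genes for region, 7339 to 9112 in females, 7802 to 10206 in males, 6 to 81 for sex in bladder, 2015 to 4228 for sex in urethra and 221 to 987 for the interaction. The lowest of the sex and interaction counts came without litter 3, and the bladder count of 81 without female bladder replicate 4. Without male urethra replicate 3 the urethra count was 2669 and the interaction count 379. List counts ranged from 14 to 19 for region, 12 to 22 for sex in bladder, 5 to 15 for sex in urethra and 12 to 21 for the interaction. Lyz2, never called between regions, changed sign with RLE factors (0.0015617), without a filter (0.016415), in DESeq2 (0.0024009), without the 2 libraries with duct markers (0.047755) and between -0.22044 and 0.21626 with libraries left out. Csf1r was 0.082929 with the mesenchyme covariate. With the smooth muscle covariate Myh11 was 0.18016, Actc1 0.0074133 and Kdr 0.062192, which were called without it (-3.7584, -3.5203 and -0.87167) and lost the call, and Erbb3, called in neither, was -0.088092. The leukocyte list in bladder turned to males without litter 1 (adjusted p = 0.869 in camera, 0.000252 without litter 4). Of 137 called gene and comparison pairs in the text, 109 were called in every setting, 20 were lost with some library or litter left out and 19 in some other setting, some of them in both. The cause of these changes was not tested. After thinning every library to 33062895 counts, 3769 genes were called by sex in urethra and 13 in bladder.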

Other observations

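The genes and libraries in this part were chosen after their values were seen. Pax2, Pax8 and Emx2, early markers of the Wolffian and Müllerian ducts, were found mainly in female urethra. Pax2 was at 21.4 ± 3.21 CPM in female and 2.29 ± 2.84 CPM in male urethra (SD, n = 4 each, log2 difference -3.21, adjusted p = 0.012 in edgeR), and Pax8 at 26.7 ± 6.34 and 1.93 ± 2.95 CPM. Emx2 was at 45.1 ± 7.35 and 6.54 ± 11 CPM. Other genes of the duct list went the other way: Osr1 was at 53.4 ± 11.2 CPM in female and 175 ± 19.9 CPM in male urethra, and Hoxa11 at 30.5 ± 3.19 and 45.4 ± 12.8 CPM. Cdh16 and Wnt9b of the same list were not called between the sexes in urethra (adjusted p = 0.571 and 0.2 in edgeR).

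Single libraries stood apart in some of these genes. In male urethra replicate 4, Cdh16 was at 52.2 CPM, Emx2 at 23 CPM, Wnt9b at 11 CPM and Pax2 at 6.44 CPM. The other 3 male urethra libraries had at most 5.94, 1.6, 1.24 and 1.63 CPM. Cdh16 and Wnt9b in replicate 4 also exceeded every female urethra library (22.3 to 36.1 and 0.61 to 1.73 CPM). Female urethra replicate 1 was rich in nuclear RNAs: Xist was at 1440 CPM against 379 to 653 CPM in the other female urethra libraries, Firre at 235 against 53.1 to 99.3 CPM and Neat1 at 117 against 28.2 to 42.7 CPM. Gm28437 was at 47.3 to 65.6 CPM in female bladder, and at 25.3 CPM in female urethra replicate 4 against 3.33 to 4.19 CPM in the other female urethra libraries.

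Among genes not on X or Y called both by sex in urethra and by region over both sexes, 870 of the male-higher genes (58.5%) and 498 of the male-lower genes (42.3%) were higher in bladder. Across genes not on X or Y, which are not independent replicates, the fold changes of both comparisons correlated at r = -0.138. The comparisons share the urethra libraries, and no test of this relation was made.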
